A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

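Messenger RNA was measured by RNA sequencing in haploid budding yeast (BY4741, MATa) grown in rich medium. Wild type cells and strains with a deletion of GCN2, GCN4 or MBF1 were left untreated or were exposed to 0.1% methyl methanesulfonate (MMS), an alkylating agent, for 1 h. Each of the 8 groups held 3 biological replicates, which gave 24 libraries. Per the labels, RNA was extracted with hot phenol, enriched for poly-A RNA and sequenced as paired reads of 150 bases.

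The authors quantified the libraries with Salmon 1.10.1 against the R64 genome build, after FastQC 0.11.9 and fastp, as named in the submitters' processing notes. The deposited value per gene used here is the estimated count, Salmon's number of fragments assigned to the gene. The authors' files also give TPM, a relative abundance based on Salmon's effective length, and both lengths in bases. The authors further deposited a comparison table for each deletion strain, made with DESeq2 1.38.3. Per the file headers, these tables hold a mean normalized count (a score), a log2 fold change with its error on the log2 scale, and a raw and an adjusted p-value.

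The files listed 5912 genes, of which 5909 were matched to the R64 gene table. For 5907 genes the deposited length was the coding length plus 400 bases, so the gene models appear to include flanking sequence. The labels and files give no strand information, so reads from overlapping or antisense genes could not be told apart, and 100 genes had over 10% of their span inside another quantified gene. A near-identical copy elsewhere in the genome (at least 90% identity by blastn 2.17.0 over at least 50% of the length) was found for 250 genes, and these are named with that limit. Values of 3 genes, and of a gene picked by the rule for named genes, are not reported here.

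Total counts per library ranged from 13518115 to 28366473. Estimated counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 8 groups and a minimum count of 10, which left 5824 genes. Libraries were scaled by TMM, and the fit had a coefficient per group over all 24 libraries with 16 residual degrees of freedom. Contrasts were tested with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all tested genes. Genes with an adjusted p under 0.05 are called changed. The deleted gene of a strain was left out of the counts and lists of its contrasts. The biological coefficient of variation over all genes was 8.49%. SE is the standard error of a log2 fold change that edgeR's test statistic implies.

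In all, 13 contrasts were tested. They were the MMS response in each of the 4 strains, the difference of each mutant's response from the wild type response (the interaction), each untreated mutant against untreated wild type, and the differences of responses between mutants. In simulated data with 200 changed genes, the fit recovered from 61.6% to 93% of 1.5-fold changes and from 87% to 98% of 2-fold changes, depending on the contrast, with 1 to 16 false calls. The simulated libraries varied independently of each other, so recovery in the real libraries may be lower.

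A set of 14 gene lists and 4 marker lists was fixed, together with the design, the contrasts, the tests and the settings to be varied, before the data were examined. Lists were tested against all other genes with camera from limma 3.58.1, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 14 lists of a contrast. A list is called changed in the text on the preset test, and the adjusted p with an estimated correlation stands beside it where the call was lost. Counts of changed members refer to the adjustment over all genes unless they are given as adjusted over the list alone. The level of the amino acid biosynthesis list was the mean log2 CPM (prior count 2) of its 53 measured members per library, and responses of this level were compared by two-sided exact permutation of the strain labels within each treatment over 400 relabelings. For the Hsf1 chaperone and ribosome biogenesis lists, list levels at equal rRNA-locus share came from a linear model with the groups and the share, or its log2, as covariates, and the scale with the smaller t is given.

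Named genes were picked by a rule. It took GCN2, GCN4 and MBF1, and the 10 largest rises and falls in the wild type MMS response without overlap between the groups' libraries. It took the 8 highest and lowest genes of each interaction, 5 of each untreated contrast and 4 of each contrast between mutants. A mean of at least 50 counts in a compared group was required. It also took the 2 list members with the smallest adjusted p per direction for the wild type response and the interactions, and ARG1, HIS4, LYS1 and SNZ1 whatever their values. Other genes in the text are said to have been chosen after their values were seen.

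Libraries of different groups that share a replicate number were mostly not alike. Of 84 such pairs, 15 had a correlation across genes of their deviations from the group mean above 0.1 (range -0.55 to 0.54). For 9 of 24 libraries the most alike library of another group had the same number, where 3 numbers were in use. The groups were therefore treated as unpaired, though pairs with different numbers were not tallied. No pair of libraries within a group was a duplicate at the level of counting noise: chi-square per degree of freedom ran from 4.33 to 194 over 24 pairs. Reads over 5 small genes that overlap ribosomal RNA genes made up 0.336% to 17.7% of a library's counts. The settings varied as fixed beforehand were other normalizations, filters and offsets, a replicate block, DESeq2 1.42.0, limma on TPM, single-library omissions, fits to the compared groups alone and a stricter threshold. Removal of a GC trend per library, the rRNA-locus share as a covariate, leaving out the genes over rRNA genes or the libraries standing apart, and thinning to equal total counts or, for untreated gcn4Δ alone, to equal usable depth were added after the data were seen, as was leaving out single libraries in the list tests.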

Results

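The deletion strains were compared with wild type to ask how the transcriptional response to MMS, a DNA alkylating agent that also damages RNA, depends on Gcn2, Gcn4 and Mbf1. Gcn2 is the kinase that phosphorylates the translation factor eIF2, Gcn4 is the transcription factor whose translation then rises, and Mbf1 is a conserved coactivator of Gcn4 that also acts at ribosomes. All values below are from 3 replicates per group (n = 3) unless stated.

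Each deleted gene was depleted in its own strain. GCN2 (YDR283C, chromosome IV, 1025070 to 1030049) had 0.576 ± 0.0711 CPM (SD, n = 3) in untreated gcn2Δ cells and 1.08 ± 0.156 after MMS, against 70 ± 5.68 and 69 ± 6.7 in wild type. GCN4 (YEL009C, chromosome V, 138918 to 139763) had 28 ± 2.7 and 25.3 ± 2.75 CPM in gcn4Δ against 971 ± 32 and 568 ± 12.3 in wild type, and its gene model includes flanking sequence that a deletion may leave in place. MBF1 (YOR298C-A, chromosome XV, 877230 to 877685) had 2.59 ± 0.332 and 0.298 ± 0.197 CPM in mbf1Δ against 281 ± 19.3 and 712 ± 39.5 in wild type. In wild type cells MBF1 mRNA rose on MMS by 1.34 on the log2 scale (SE 0.10, adjusted p = 4.14e-11) and GCN4 mRNA fell by 0.77 (SE 0.08, adjusted p = 6.05e-09). GCN2 mRNA had a log2 change of -0.02 (SE 0.11, adjusted p = 0.858), and 0.45 by limma on TPM, where all genes shifted by 0.554. GCN4 mRNA fell further in gcn2Δ and in mbf1Δ, by 1.54 and 1.57, and both interactions passed the test (-0.76, SE 0.11, and -0.80, SE 0.11). MBF1 rose more in gcn2Δ than in wild type (interaction 0.56, SE 0.14, adjusted p = 0.00417), and GCN2 fell in gcn4Δ relative to wild type (interaction -0.57, SE 0.16, adjusted p = 0.00636).

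**Figure D1:**
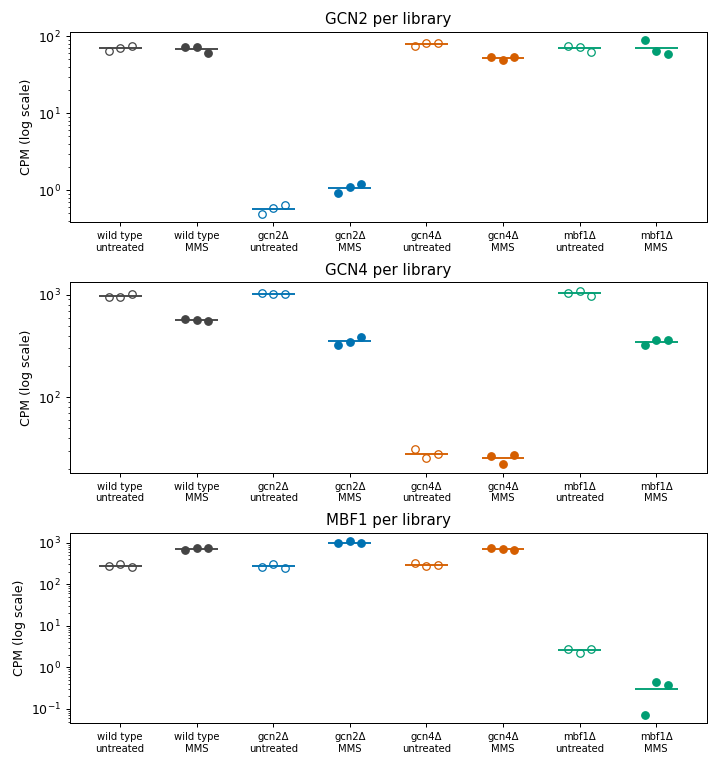
CPM on a log axis of GCN2, GCN4 and MBF1 in each of the 24 libraries; open circles are untreated, filled circles are MMS-treated and lines are group means (n = 3). In its own deletion strain each gene lay far below wild type, at 0.576 CPM for GCN2, 28 for GCN4 and 2.59 for MBF1 in untreated cells.

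MMS changed most of the wild type transcriptome. The largest rises were in stress and damage genes: HSP12, a small heat shock protein, rose 160-fold (log2 7.32, SE 0.24), and DDR2 rose 79.9-fold (log2 6.32, SE 0.21). DDI2 and DDI3, near-identical copies of a DNA damage-induced cyanamide hydratase that reads cannot separate well, rose 99.6-fold and 74.9-fold. Arginine genes rose with them: ARG3 rose by 4.97 on the log2 scale (SE 0.18), ARG4 by 4.70 (SE 0.061) and ARG1 by 4.34 (SE 0.095). The largest falls were in HXT2, a glucose transporter (log2 -6.29, SE 0.18), DBP2, an RNA helicase (-6.08, SE 0.12), URA7, a CTP synthase (-5.81, SE 0.13), and OLE1, the fatty acid desaturase (-5.67, SE 0.22). Further rises above 30-fold were those of TFS1, an inhibitor of carboxypeptidase Y (40.6-fold), TSA2, a peroxiredoxin (37.6-fold), RTC3 (36.9-fold), PGM2, a phosphoglucomutase (30.9-fold), and RTC2, a vacuolar transporter (30.6-fold). INA1, REA1, NSR1, DHR2, URA1 and ANB1 had log2 changes of -5.25 to -5.12, of which REA1, NSR1 and DHR2 act in ribosome assembly and ANB1 has a copy, HYP2, with 91.1% identity.

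Ribosome biogenesis fell as a group, with all 75 measured members lower and a median of -3.66. HAS1 had -4.94 (SE 0.074) and SDA1 -4.80 (SE 0.082). Of 132 cytosolic ribosomal protein genes, 131 fell (median -3.15), among them RPL21B (-3.36, SE 0.067, with a copy of 93.8% identity) and RPS22B (-3.27, SE 0.062), while RPL15B, with a copy of 93.3% identity, rose by 1.31. All 21 cytosolic aminoacyl-tRNA synthetase genes fell (median -1.78), with MES1 at -2.4 and GRS1 at -2.36. The Msn2/Msn4 environmental stress list rose in 29 of 30 members (median 3.55), with UBI4, the polyubiquitin gene, at 4.21 (SE 0.074) and the trehalase NTH1 at 3.66 (SE 0.07). The Yap1 oxidative stress list rose in 21 of 22 (median 1.76), including GTT2 (4.17) and PRX1 (3.14). The proteasome list rose in 33 of 34 (median 1.11), including PRE2 (2.09) and RPT2 (1.69). The DNA damage list rose in 24 of 32 and fell in 6 (median 1.01), with DDI1 at 3.10, RAD16 at 1.70 and OGG1 at -1.80; adjusted over the list alone, 7 fell. These 7 lists passed camera with both correlations, with adjusted p from 0.00186 for ribosome biogenesis to 0.0336 for the proteasome and Msn2/Msn4 lists with an estimated correlation.

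The amino acid biosynthesis list, made of targets of general amino acid control, rose in 32 of 53 members, fell in 16 and had 5 not called (median 0.86). LYS1 rose 9.53-fold (log2 3.25, SE 0.07), SNZ1, a vitamin B6 gene under the same control, rose 9.73-fold (3.28, SE 0.084), ARG7 rose by 3.22 and HIS4 by 1.45 (SE 0.11), while LEU9 fell by 2.10 and CYS4 by 1.89. The list passed with the preset correlation (adjusted p = 4.56e-05), with adjusted p = 0.223 with an estimated correlation. Hsf1 chaperones rose in 15 and fell in 8 of 24 (median 1.02), with HSP78 at 4.38, HSP82 at 2.4 (copy HSC82, 91.8% identity), SSE1 at -1.18 and YDJ1 at -1.03; adjusted p = 0.0107 preset, and adjusted p = 0.136 with an estimated correlation. All 11 histone genes fell (median -1.92; HTB2 -4.11, HTA1 -2.73 with a copy; adjusted p = 0.000109, and adjusted p = 0.0743 with an estimated correlation, which was 0.0479 and 0.0319 without untreated wild type replicates 1 and 3). The GCN pathway and collided ribosome list fell in 22 and rose in 9 of 34 (median -0.61), with NEW1 at -2.81, GCD11, the gamma subunit of eIF2, at -2.52 and RQC1 at 0.72. Nitrogen catabolite genes rose in 20 and fell in 6 of 28 (UGA3 2.37, UGA1 2.01, GLN1 -2.06, MEP3 -1.02), and unfolded protein response genes rose in 14 and fell in 3 of 18 (ERO1 2.03, MPD1 1.86, IRE1 -0.76). These calls had adjusted p = 0.189, 0.267 and 0.189 with an estimated correlation, in that order. The sulfur and methionine list split, with 13 rises and 8 falls among 26 (STR3 2.98, MET22 1.20, SAM2 -2.33; adjusted p = 0.574). For these lists the counts adjusted over the list alone were the same.

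In wild type 4839 of 5821 genes were called, 2442 higher and 2397 lower, of which 1155 and 1255 changed at least 2-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg). On the TPM scale, which has no normalization between libraries, the median of all genes was shifted by 0.554 in this contrast and by 0.546 to 0.643 in the mutants' responses, so directions below are relative to the bulk of genes after TMM. In the mutants 2406 genes rose and 2350 fell in gcn2Δ, 2367 and 2480 in gcn4Δ, and 2487 and 2336 in mbf1Δ. Fewer of them reached 2-fold, 979 and 1146 in gcn2Δ, 1025 and 1186 in gcn4Δ, and 1050 and 1195 in mbf1Δ. The SD of the log2 changes over all genes was 1.34, 1.28 and 1.45 in that order, against 1.55 in wild type.

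On average the amino acid biosynthesis list rose in wild type and fell in each mutant, relative to the bulk of genes after TMM. Its mean level rose in wild type from 7.78 ± 0.082 to 8.57 ± 0.038 log2 CPM (SD, n = 3), and fell in gcn2Δ from 7.60 ± 0.031 to 6.56 ± 0.08, in gcn4Δ from 7.42 ± 0.066 to 6.83 ± 0.019 and in mbf1Δ from 7.77 ± 0.043 to 7.11 ± 0.11. The responses were 0.80 (SE 0.052) in wild type, -1.04 (SE 0.049) in gcn2Δ, -0.59 (SE 0.04) in gcn4Δ and -0.66 (SE 0.067) in mbf1Δ. As mean log2(TPM + 1) they were 1.42, -0.40, 0.02 and 0.06, on a scale where the median of all genes was shifted by 0.554, 0.546, 0.576 and 0.643, in the order of wild type, gcn2Δ, gcn4Δ and mbf1Δ. Of the 53 members, 37 fell and 5 rose in gcn2Δ, 33 fell and 14 rose in gcn4Δ, and 32 fell and 15 rose in mbf1Δ. On that list the calls were lower with the preset correlation in each mutant (adjusted p = 1.05e-06, 0.00341 and 0.0105), with adjusted p = 0.16, 0.405 and 0.427 with an estimated correlation. ARG1 rose by 0.95 in mbf1Δ and by 1.36 in gcn4Δ and had 0.18 (SE 0.088, adjusted p = 0.0685) in gcn2Δ, against 4.34 in wild type. HIS4 fell, with -2.04, -1.36 and -1.14 in gcn2Δ, gcn4Δ and mbf1Δ. LYS1 rose by 1.07, 1.45 and 1.40. SNZ1 had -0.08 in gcn2Δ (adjusted p = 0.361) and -0.20 in gcn4Δ (adjusted p = 0.0277), which were 0.55 and 0.40 by limma on TPM, where all genes shifted by 0.546 and 0.576, and it rose by 0.22 in mbf1Δ.

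**Figure D2:**
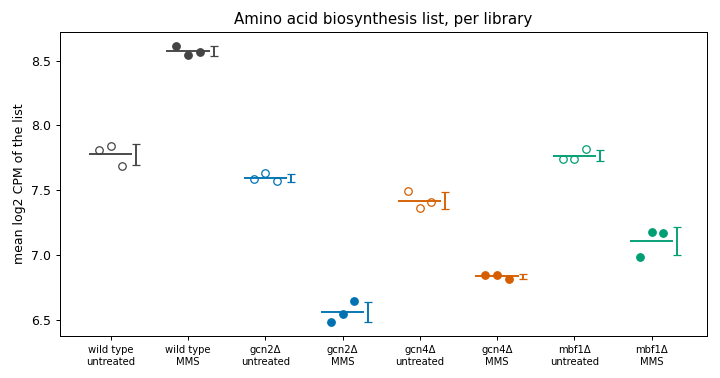
Mean log2 CPM of the 53 measured amino acid biosynthesis genes in each library; open circles are untreated, filled circles MMS-treated, lines are group means and bars are 1 SD (n = 3). The level rose by 0.80 in wild type and fell by 1.04 in gcn2Δ, 0.59 in gcn4Δ and 0.66 in mbf1Δ.

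Tested on the level itself, the mutant responses differed from wild type by -1.84 (gcn2Δ, SE 0.072), -1.38 (gcn4Δ, SE 0.065) and -1.45 (mbf1Δ, SE 0.085), with exact permutation p = 0.1, 0.1 and 0.06 (adjusted p = 0.15 for each over 6 comparisons, exact permutation). Every untreated gcn2Δ and gcn4Δ library lay below every untreated wild type one, so relabeling untreated libraries alone never gave a smaller difference. For these mutants p could not fall under 0.1 at any size of the MMS effect, and the test could not decide. For mbf1Δ the p of 0.06 was likewise set by the untreated libraries, since treated mbf1Δ and wild type libraries did not overlap. The response of gcn2Δ lay below that of gcn4Δ by -0.45 (SE 0.063, exact permutation p = 0.005, the smallest these relabelings can give, adjusted p = 0.03). Every untreated gcn4Δ library lay below every untreated gcn2Δ one, and every treated one above. Both separations produced this p, so it is no test of the MMS effect alone. The response of mbf1Δ differed from gcn2Δ by 0.38 (SE 0.083, exact permutation p = 0.14) and from gcn4Δ by -0.07 (SE 0.078, exact permutation p = 0.765). Every untreated mbf1Δ library lay above every untreated gcn2Δ one, so the p of 0.14 could not have fallen under 0.1 either. As mean log2(TPM + 1) the differences from wild type were -1.82, -1.40 and -1.36 with exact permutation p = 0.01, 0.02 and 0.025, and that of mbf1Δ from gcn2Δ was 0.46 (exact permutation p = 0.02). Without untreated wild type replicate 2 the difference of mbf1Δ from wild type was -1.48 and passed 0.05.

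**Figure D3:**
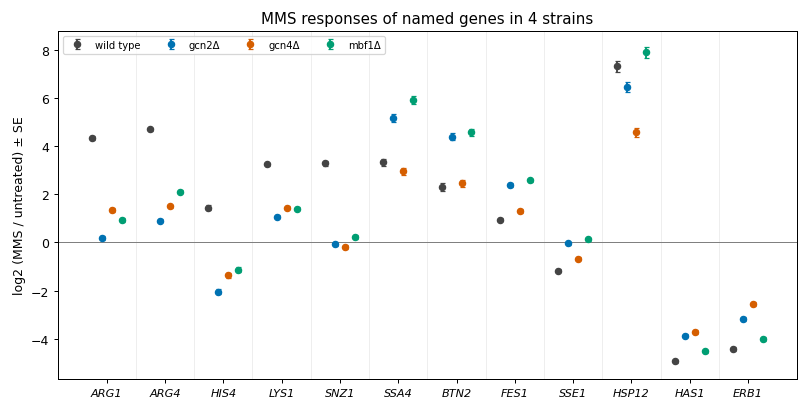
Log2 ratio of MMS-treated to untreated expression with its SE for 12 genes in the 4 strains (edgeR, n = 3 per group). ARG1 responded by 4.34 in wild type and by 0.95 in mbf1Δ, whereas SSA4 lay higher in gcn2Δ and mbf1Δ than in wild type, by 1.84 and 2.60.

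Without GCN2, amino acid genes were among those whose MMS response lay lowest relative to wild type, over genes with a mean of at least 50 counts in a compared group. The response of ARG1, argininosuccinate synthetase, was lower than in wild type by a factor of 17.9 (interaction log2 -4.17, SE 0.13, adjusted p = 5.08e-17). YOR302W, the leader peptide upstream of CPA1, had a log2 difference of -4.14 (SE 0.24), and ARO5 had -4.05 (SE 0.19). ARG7 (-3.96, SE 0.073), RTC2 (-3.84, SE 0.31), ARG4 (-3.80, SE 0.078) and TMT1 (-3.66, SE 0.11) followed, and HIS4, SNZ1 and LYS1 had -3.49, -3.36 and -2.18. Of the 53 list members 48 were lower, 1 was higher (CYS3, 0.71) and 4 were not called (median -1.66; 49 lower and 2 higher adjusted over the list alone). The amino acid permease gene AGP1 (-2.0, SE 0.17) and UGA3, a regulator of GABA use (-2.01, SE 0.13), were also lower.

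Other groups differed in gcn2Δ as well. Hsf1 chaperones were higher in 16 of 24 and lower in 1 (HSP78, -0.41; median 0.76), with BTN2, an aggregate-sorting factor, at 2.08 (SE 0.22), SSA4, a stress-induced Hsp70, at 1.84 (SE 0.20), FES1, an Hsp70 nucleotide exchange factor, at 1.43 (SE 0.10), and SSE1, an Hsp110, at 1.15 (SE 0.09). Ribosome biogenesis fell less, with 71 of 75 members higher than in wild type (median 0.90; HAS1 1.07, UTP13 1.05, and ESF1 at 1.67). Amino acid biosynthesis (adjusted p = 3.49e-06), Hsf1 chaperones (adjusted p = 0.00534) and ribosome biogenesis (adjusted p = 0.00627) held with an estimated correlation. Ribosomal protein genes were higher in 63 of 132 (median 0.30; RPL18B 1.09, RPL15B -0.75), the Msn2/Msn4 list was lower in 24 of 30 (median -0.80; DCS2 -1.52, NTH1 -0.81, SSA3 0.49), and 7 of 21 synthetase genes were lower and 3 higher (KRS1 -1.16, DPS1 -1.09, CRS1 0.50, FRS1 0.30). Those calls had adjusted p = 0.411, 0.3 and 0.411 with an estimated correlation. FLR1, a multidrug transporter of the Yap1 list, was higher by 1.73 (SE 0.18), HXT10 by 1.75 (SE 0.32) and TSA2 lower (-1.62, SE 0.22). MET22 (-1.27) and STR3 (-2.18) were lower, MHT1 (1.15) and MET8 (0.96) higher, RNR4 lower (-0.50), OGG1 higher (1.03), and HHT2 and HTA1, both with near-identical copies, lower (-0.87 and -0.83). Of 26 sulfur and methionine genes 10 were lower and 4 higher (camera adjusted p = 0.0239, and 0.411 with an estimated correlation). Of 28 nitrogen catabolite genes 10 were lower and 1 higher (camera adjusted p = 0.00287, and 0.327 with an estimated correlation). Both lists were also called lower in the mbf1Δ interaction (camera adjusted p = 0.00323 and 0.00479, and 0.324 each with an estimated correlation). YRF1-6 (2.71, SE 0.95) has identical copies at other telomeres and FYV5 (1.68, SE 0.57) lies mostly inside ADF1, so neither can be assigned to its gene. In all 1082 genes were higher and 1009 lower, 124 and 221 of them at least 2-fold, and the count of 2091 was 1295 by limma on TPM.

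Without GCN4, amino acid genes were again among the lowest, over genes with that many counts. ARO5 was lower, with a log2 difference of -4.43 (SE 0.19), as were ARG7 (-3.87, SE 0.073), TMT1 (-3.62, SE 0.11), RTC2 (-3.55, SE 0.32), SNZ1 (-3.48, SE 0.12) and ARG4 (-3.20, SE 0.077), and ARG1, HIS4 and LYS1 had -2.98, -2.81 and -1.80. Of the 53 members 46 were lower and 2 higher (CYS3 1.22, CYS4 0.36; median -1.33; 47 lower and 3 higher adjusted over the list alone). Ribosomal protein genes fell less than in wild type in 124 of 132 (median 1.00), with RPS22A at 1.54 (SE 0.097) and RPS9B at 1.32 (SE 0.096), both with copies of over 90% identity. Ribosome biogenesis fell less in 73 of 75 (median 1.17), with ERB1 at 1.86 (SE 0.11) and UTP21 at 1.46 (SE 0.084).

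ASC1, a ribosome-bound scaffold protein, was higher by 2.05 (SE 0.27), FPR4 by 1.97 (SE 0.20) and DRS1, a biogenesis helicase, by 1.90 (SE 0.22). RBG1 and RBG2, ribosome-associated GTPases, were higher by 1.17 and 1.37, and 14 of 33 members of the GCN pathway and collided ribosome list were higher and 2 lower (median 0.21; adjusted p = 0.00598, and adjusted p = 0.31 with an estimated correlation). That list was also called higher by camera in the gcn2Δ interaction, with 11 higher and 1 lower (adjusted p = 0.00593, and 0.272 with an estimated correlation). In the mbf1Δ interaction 9 were higher and 1 lower (adjusted p = 0.0402, and 0.391 with an estimated correlation). HSP12 (-2.74, SE 0.30) and HOR7 (-1.74, SE 0.14) were lower. Untreated gcn4Δ already had more HSP12 than untreated wild type, and that level goes into the HSP12 difference. Of 30 Msn2/Msn4 genes 20 were lower (median -0.74, camera adjusted p = 7.5e-07, and adjusted p = 0.31 with an estimated correlation). Hsf1 chaperones did not move together: 5 were higher and 4 lower (median -0.03, adjusted p = 0.73), with SSE1 at 0.50, YDJ1 at 0.33, HSP26 at -1.07 and HSP78 at -1.05. AGP1 (-1.58), UGA3 (-1.97), MET22 (-1.37) and STR3 (-1.61) were lower, SAM1 (1.16), FLR1 (1.60), FRS1 (0.65) and CRS1 (0.74) higher, and KRS1 (-0.67), PRE2 (-0.41), PRE3 (-0.41) and RAD53 (-0.55) lower. With an estimated correlation, amino acid biosynthesis (adjusted p = 0.000102), ribosomal proteins (adjusted p = 0.00834) and ribosome biogenesis (adjusted p = 0.000923) held. The share of counts over ribosomal RNA genes was 1.28% in untreated and 0.489% in treated gcn4Δ, against 14.4% and 15.4% in wild type. With that share as a covariate, the ribosomal protein list had a median of 0.96 (adjusted p = 0.028) and ribosome biogenesis 1.19 (adjusted p = 0.0104), with an estimated correlation. Libraries of gcn4Δ and wild type did not overlap in share, so that fit extends a trend within groups. In all 1092 genes were higher and 956 lower, 261 and 152 of them at least 2-fold, and 1344 were called at an adjusted p under 0.01. The count of 2048 was 3086 with the rRNA-locus share as a covariate and 1315 by limma on TPM. YLR154C-G (2.46), YLR162W (2.34) and RRT15 (2.19) lie over ribosomal RNA genes. YCR050C lies almost wholly inside ARE1 and had 0 CPM in untreated wild type, so its log2 difference (-9.29, SE 3.5) has no exact size.

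Without MBF1, the response of ARG1 was lower than in wild type by a factor of 10.5 (interaction log2 -3.40, SE 0.12, adjusted p = 4.06e-15). SNZ1 was lower (-3.06, SE 0.12), as were YOR302W (-2.97, SE 0.23), ARO5 (-2.96, SE 0.20), RTC2 (-2.87, SE 0.33), TMT1 (-2.74, SE 0.11), HIS4 (-2.59, SE 0.15) and ARG4 (-2.59, SE 0.077), and ARG7 and LYS1 had -2.27 and -1.85. Of the 53 amino acid genes 48 were lower, none was higher and 5 were not called (median -1.38; 50 lower adjusted over the list alone). Hsf1 chaperones were higher in 19 of 24, with none lower (median 0.89): SSA4 was higher by 2.60 (SE 0.20), BTN2 by 2.25 (SE 0.23), FES1 by 1.63 (SE 0.10), CPR6, a cyclophilin, by 1.35 (SE 0.17) and SSE1 by 1.31 (SE 0.091). Both lists held with an estimated correlation (adjusted p = 3.44e-06 and 4e-05).

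Ribosomal protein genes were not called as a list in the mbf1Δ interaction (7 higher and 11 lower of 132, median -0.05, adjusted p = 0.72; 5 and 2 adjusted over the list alone), with RPL18B at 0.86 and RPS15 at -0.36. Ribosome biogenesis was higher in 49 of 75 (median 0.44; NOP14 1.00, UTP13 0.60; adjusted p = 5e-13, and adjusted p = 0.136 with an estimated correlation). The proteasome list was higher in 10 of 34 (median 0.19; RPN11 0.33, RPT2 0.32; adjusted p = 0.00566, and adjusted p = 0.324 with an estimated correlation), and 8 of 21 synthetase genes were lower (median -0.20; KRS1 -0.92, DPS1 -0.89; adjusted p = 4.69e-06, and adjusted p = 0.136 with an estimated correlation). RQC2, a ribosome quality control factor, was higher by 0.88 (SE 0.15) and SMY2 by 0.69 (SE 0.086), while AGP1 (-1.61), UGA3 (-1.56), STR3 (-1.86) and MET22 (-0.95) were lower. ATR1 (-1.18), TSA2 (-1.21), RNR2 (-0.68), RNR4 (-0.51) and HTB2 (-0.56) were lower, and FLR1 (1.32), ERO1 (0.64), HXK1 (0.79) and DDI1 (0.49) higher. In all 675 genes were higher and 719 lower, 36 and 126 of them at least 2-fold, and 782 were called at an adjusted p under 0.01. The count of 1394 was 2289 with the rRNA-locus share as a covariate and 794 by limma on TPM.

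**Figure D4:**
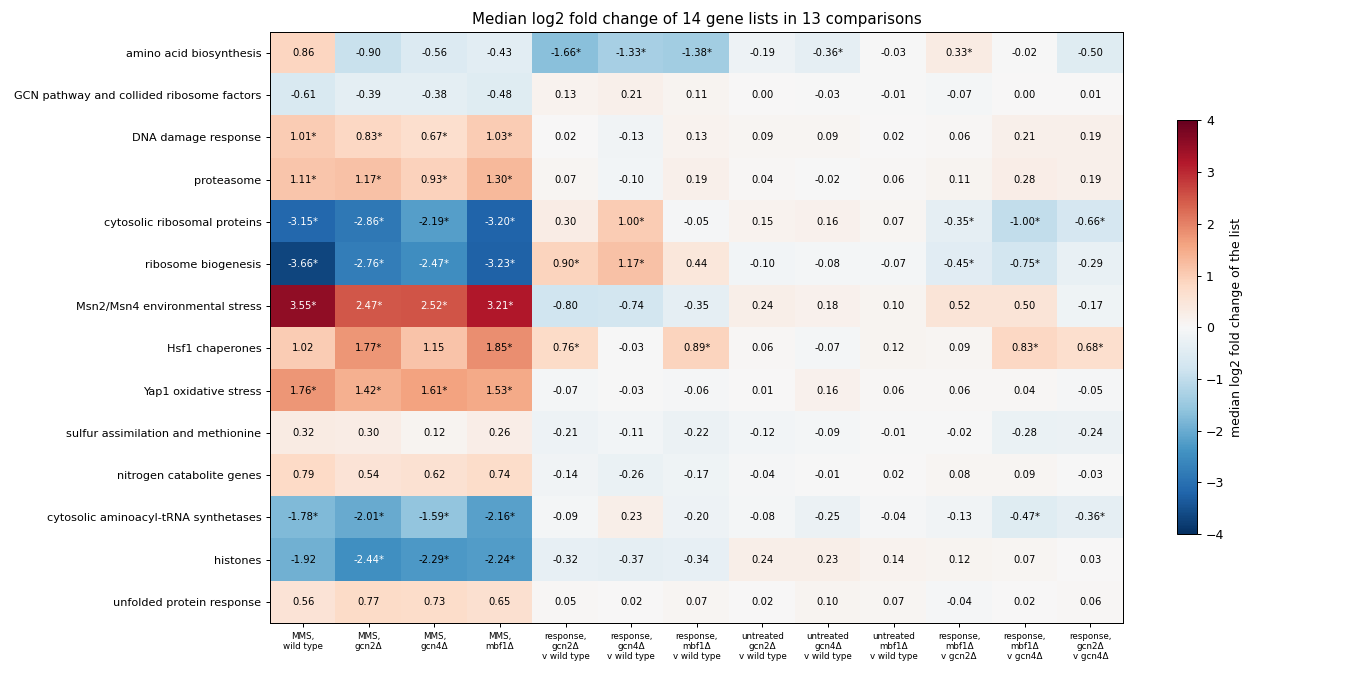
Median log2 fold change (color scale) of 14 gene lists in the 13 comparisons, where columns headed response give differences between MMS responses; asterisks mark lists with adjusted p under 0.05 in camera with a preset and with an estimated correlation. The amino acid list has medians of -1.66, -1.33 and -1.38 in gcn2Δ, gcn4Δ and mbf1Δ relative to wild type, and Hsf1 chaperones have 0.76, -0.03 and 0.89.

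The interactions overlapped. Of 5818 genes, 356 were lower and 265 higher in all 3, and the former held 45 of the 53 amino acid genes. The gcn2Δ and mbf1Δ interactions shared 561 higher and 603 lower genes, with 1 called in opposite directions. The gcn2Δ and gcn4Δ interactions shared 594 and 554, with 21 opposite, and the gcn4Δ and mbf1Δ interactions shared 269 and 367, with 62 opposite. Independent lists of those sizes would share 125 and 124, 203 and 165, and 127 and 118 genes, in that order. The Pearson correlation across genes, which are not independent replicates, was 0.791 for gcn2Δ and mbf1Δ, 0.718 for gcn2Δ and gcn4Δ and 0.576 for gcn4Δ and mbf1Δ. In 25 simulations of unchanged mutants against the shared wild type it was 0.528, 0.535 and 0.531. The covariances were 0.278, 0.276 and 0.215, against 0.0315, 0.0298 and 0.0308 in the simulations. The simulations hold independent variation between libraries, so an effect common to all wild type libraries, which all 3 interactions used, was not separated.

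Compared directly, some amino acid genes had a higher log2 response in mbf1Δ than in gcn2Δ, while the mean level of the list differed by 0.38 with exact permutation p = 0.14 (adjusted p = 0.168). The response of ARG7 was higher in mbf1Δ by 1.69 (SE 0.071, adjusted p = 3.3e-13), and 24 of 53 amino acid genes were higher and 1 lower (median 0.33; 31 and 2 adjusted over the list alone; adjusted p = 0.00771 with an estimated correlation). HSP12 (1.44, SE 0.31) and HSP26 (1.28, SE 0.20) were higher. MUM3, whose gene model meets that of its neighbour MBF1, was lower (-2.15, SE 0.17), as were the cell wall genes TOS6 (-1.55) and SCW10 (-1.17), and INA1 (-1.02). Ribosome biogenesis was lower in 39 of 75 (median -0.45; 65 adjusted over the list alone; adjusted p = 0.0056 with an estimated correlation) and ribosomal proteins in 57 of 132 (median -0.35; 95 adjusted over the list alone; adjusted p = 0.0492 with an estimated correlation). That last value stayed under 0.05 in 4 of 12 omissions of a single library and was above it in the others: it was 0.0568 and 0.0626 without untreated gcn2Δ replicates 1 and 3, and 0.0502 and 0.0758 without treated gcn2Δ replicates 1 and 2. It was 0.06 and 0.0703 without untreated mbf1Δ replicates 1 and 2, and 0.063 and 0.106 without treated mbf1Δ replicates 2 and 3. The Msn2/Msn4 list was higher in 13 of 30 (median 0.52; 17 adjusted over the list alone; adjusted p = 1.17e-16, and adjusted p = 0.0506 with an estimated correlation, which was 0.0202 and 0.0457 without untreated and treated mbf1Δ replicate 1). In all 157 genes were higher and 235 lower, and 6 of 100 groupings of the libraries, the real one included, gave as many calls, so chance was not excluded for this count. The count of 392 fell to 103 in a fit to the 4 groups alone, to 129 by limma on TPM and to 158 at an adjusted p under 0.01, and rose to 602 with a GC trend removed, to 684 with the rRNA-locus share as a covariate and to 597 without the 3 libraries standing apart. It was 231 without untreated gcn2Δ replicate 1, and 221 and 260 without untreated mbf1Δ replicates 2 and 3.

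Against gcn4Δ, the chaperone genes set the other mutants apart. SSA4 responded more in mbf1Δ by 2.97 (SE 0.20) and in gcn2Δ by 2.21 (SE 0.20), and BTN2 by 1.95 (SE 0.21) in gcn2Δ. HSP12, which belongs to the Msn2/Msn4 list, responded more in mbf1Δ by 3.32 (SE 0.29) and in gcn2Δ by 1.88 (SE 0.27). Untreated gcn4Δ already had more HSP12 than untreated wild type, and that level goes into both HSP12 differences. Of the 24 Hsf1 chaperones 22 were higher in mbf1Δ (median 0.83) and 20 in gcn2Δ (median 0.68), and none was lower. Ribosomal protein genes fell further in both, with 120 of 132 lower in mbf1Δ (median -1.0) and 111 in gcn2Δ (median -0.66), among them RPL4B at -2.04 and -1.68, whose copy RPL4A is 99.3% identical. ASC1 was lower in mbf1Δ (-2.03, SE 0.26) and GSY1, a glycogen synthase, in gcn2Δ (-2.09, SE 0.43). Synthetase genes were lower in 21 of 21 (median -0.47) and 20 of 21 (median -0.36). Ribosome biogenesis was lower in 66 of 75 in mbf1Δ (median -0.75) and in 32 in gcn2Δ (median -0.29; adjusted p = 5.32e-07, and adjusted p = 0.249 with an estimated correlation). Amino acid genes were lower in gcn2Δ in 31 of 53 (median -0.50; adjusted p = 5.7e-13, and adjusted p = 0.096 with an estimated correlation), and in mbf1Δ 12 were higher and 17 lower (median -0.02, mean -0.06, camera direction up, adjusted p = 0.993). With an estimated correlation Hsf1 chaperones (adjusted p = 0.000196 and 0.000175), ribosomal proteins (0.00302 and 0.0222) and synthetases (0.0281 and 0.0301) held for both mutants; without treated gcn2Δ replicate 3 the gcn2Δ values of the ribosomal protein and synthetase lists were 0.0574 each. The counts were 1223 higher and 1328 lower for mbf1Δ and 841 and 1064 for gcn2Δ. By limma on TPM they were 1312 and 954 in all, at an adjusted p under 0.01 they were 1598 and 1034, and with the rRNA-locus share as a covariate that of gcn2Δ was 3414. No gcn4Δ library had a share above 1.48%, and no gcn2Δ or mbf1Δ library had one below 6.8%. In these comparisons a difference that goes with the share therefore cannot be told apart from the strain.

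Untreated gcn4Δ had lower amino acid genes, with 31 of 53 lower and none higher (median -0.36; 35 and 1 adjusted over the list alone; adjusted p = 0.0325 with an estimated correlation, 0.0559 without untreated wild type replicate 3 and 0.0548 without untreated gcn4Δ replicate 2), and 13 of 21 synthetase genes were lower (median -0.25; adjusted p = 1.74e-08, and adjusted p = 0.0909 with an estimated correlation). These medians were 0.08 and 0.21 by limma on TPM, where all genes shifted by 0.41. HSP12 was higher in gcn4Δ by 1.79 (SE 0.25), ECM11 by 2.08 (SE 0.46) and MTC7 by 1.93 (SE 0.53), and HSP30 was lower (-1.79, SE 0.30). YLR162W, YLR154C-G and RRT15 were lower (-8.23, -8.18 and -8.04), as was TAR1 (-2.96). They overlap ribosomal RNA genes, and the share of counts over that locus was 1.28% ± 0.254 (SD, n = 3) in untreated gcn4Δ against 14.4% ± 3.33 in wild type, 7.05% ± 0.32 in gcn2Δ and 11.5% ± 2.92 in mbf1Δ. Untreated gcn2Δ had lower AIM14 (-1.88, SE 0.078), PHO89, a phosphate transporter (-1.57, SE 0.23), MRX10, the gene beside GCN2 (-1.14, SE 0.11), and PHO84 (-0.91, SE 0.20), and higher RGI1 (1.22, SE 0.22), YNL146C-A (1.37) and GSP2 (0.58). The gene model of MRX10 may meet that of GCN2. Untreated mbf1Δ had higher MUM3 (1.58, SE 0.13) and lower PHO89 (-1.45, SE 0.24) and PHO12 and PHO11, acid phosphatases that are 99.7% identical (-0.97 and -0.91). In gcn2Δ 3 of 53 amino acid genes were lower (26 adjusted over the list alone; median -0.19, and 0.13 by limma on TPM, where all genes shifted by 0.314; adjusted p = 9.93e-11, and adjusted p = 0.385 with an estimated correlation), and in mbf1Δ none was called (median -0.03, adjusted p = 0.286).

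**Figure D5:**
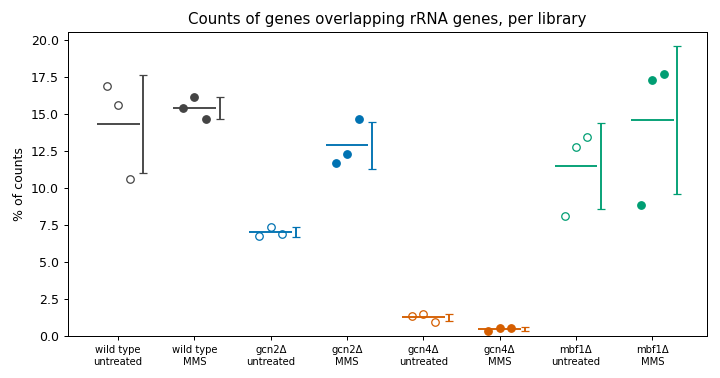
Percentage of each library's counts over the 5 genes that overlap ribosomal RNA genes; open circles are untreated, filled circles MMS-treated, lines are group means and bars are 1 SD (n = 3). Untreated gcn4Δ averaged 1.28% and untreated wild type 14.4%.

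The untreated contrasts called 535 higher and 588 lower genes in gcn4Δ, 7 and 18 in gcn2Δ and 1 and 8 in mbf1Δ (edgeR; 2067, 1517 and 275 genes at an unadjusted p under 0.05). These counts depended on single libraries, and the difference between them was not tested. For gcn4Δ the count of 1123 was 517, 522 and 1916 without untreated wild type replicates 1, 2 and 3, and 707 and 563 without untreated gcn4Δ replicates 2 and 3. For gcn2Δ the count of 25 was 7, 11 and 1156 without untreated wild type replicates 1, 2 and 3, 7 and 9 without untreated gcn2Δ replicates 1 and 3, and 88 and 153 without MMS-treated gcn2Δ replicates 1 and 3. It was 57 without untreated mbf1Δ replicate 1, and 554 and 47 without MMS-treated mbf1Δ replicates 1 and 3. For mbf1Δ the count of 9 was 5 without untreated mbf1Δ replicate 3. Without the 3 libraries standing apart, of which untreated wild type replicate 3 is the single wild type one, the counts were 2502 in gcn4Δ and 2031 in gcn2Δ, and with the rRNA-locus share as a covariate 192 of the 1123 gcn4Δ calls were kept. By DESeq2 they were 395 in gcn2Δ and 17 in mbf1Δ, and by limma on TPM, where all genes shifted, 4288, 2860 and 14 in gcn4Δ, gcn2Δ and mbf1Δ.

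The authors' deposited table for each strain was set beside the fit here, and its values lay nearest to interactions. Across genes the log2 fold changes of the authors' deposited table for gcn2Δ had a Pearson correlation of 0.887 with the gcn2Δ interaction, and those for gcn4Δ and mbf1Δ had 0.832 and 0.735 with theirs, while the table for mbf1Δ had 0.78 with the gcn2Δ interaction. In the authors' deposited table ARG1 had -4.12 in gcn2Δ, -3.0 in gcn4Δ and -3.42 in mbf1Δ, and SSA4 had 1.76 in gcn2Δ and 2.48 in mbf1Δ. The authors' deposited tables call 2229 genes for gcn2Δ, 2056 for gcn4Δ and 1574 for mbf1Δ. All of them (100%) had the same sign here in the interaction of the same strain, and 2056, 1886 and 1348 were also called here.

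Marker genes were read for mating type and auxotrophies. Summed over 7 MATa genes the libraries held 2540 ± 203 CPM in untreated wild type and 1260 to 2580 over the 8 group means, against 48 to 122 over 4 MATalpha genes, of which SAG1 made up 45.6 CPM in untreated wild type. Of the 7 MATa genes 5 were lower in the mbf1Δ interaction (median -0.39), 1 was lower in that of gcn2Δ (median -0.26) and 1 higher in that of gcn4Δ (median 0.10). URA3 and MET17 had a total of 0 counts in every group, and the group means of LEU2 ran from 0.258 to 0.978 CPM. HIS3 rose in wild type from 64.9 ± 1.42 to 166 ± 4.14 CPM and LYS2 from 282 ± 16.5 to 558 ± 23.6, and both are targets of general amino acid control. The BY4741 background carries a deletion at the HIS3 locus, for which HIS3 was left out of the amino acid list. Its counts therefore need not come from an intact gene. HIS3 went from 62.4 to 34.6 CPM in gcn2Δ, 52.5 to 45.9 in gcn4Δ and 61.7 to 48.8 in mbf1Δ, and LYS2 from 247 to 94, 188 to 82.3 and 270 to 157. Summed over 8 meiosis and sporulation genes the level was 94.4 ± 10.4 CPM in untreated and 136 ± 3.66 in treated wild type. Of those genes 5 rose and 1 fell in wild type, none was called in the gcn2Δ or mbf1Δ interactions and 2 were higher in the gcn4Δ interaction.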

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

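The regroupings of libraries were planned, and all the tests of explanations reported here were chosen after the result was seen. Tests of the differences between strains singled out the results that follow.

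The response to MMS differed from that of wild type in 2091 genes in gcn2Δ, 2048 in gcn4Δ and 1394 in mbf1Δ, and between mutants in 392 genes (mbf1Δ against gcn2Δ), 2551 (mbf1Δ against gcn4Δ) and 1905 (gcn2Δ against gcn4Δ). Over 100 of the 200 possible groupings of the 12 libraries, the real one included, the share with as many calls was set against 0.05. It lay under 0.05 for gcn2Δ (4 as large, highest other 2916), gcn4Δ (1, highest other 1840), mbf1Δ (4, highest other 1909), mbf1Δ against gcn4Δ (1, highest other 2449) and gcn2Δ against gcn4Δ (3, highest other 2070), without adjustment over these comparisons. For gcn2Δ, gcn4Δ, mbf1Δ and gcn2Δ against gcn4Δ, the highest other count came from exchanging untreated libraries alone. For mbf1Δ against gcn4Δ it came from exchanging all 6 treated and 4 untreated libraries. Apart from sign, that equals exchanging only replicate 1 of the untreated strains. Such regroupings keep the treated strain difference whole, so the shares are no clean measure of chance. The share was above 0.05 for mbf1Δ against gcn2Δ (6, highest other 2583), where chance was not excluded. That highest count, several times the real 392, came from a regrouping that exchanged all 6 untreated libraries and 2 treated ones, gcn2Δ replicate 3 and mbf1Δ replicate 1. The latter is 1 of the 3 libraries standing apart. A count of calls does not depend on sign, so this regrouping equals one that leaves the untreated libraries in place. It sets treated gcn2Δ replicate 3 and mbf1Δ replicates 2 and 3 against the other treated libraries. Their rRNA-locus shares were 14.7%, 17.3% and 17.7% against 11.7%, 12.3% and 8.85%. Differences between treated libraries that do not follow the strain can thus go with more calls than the real grouping gave. What lies behind that count was not tested. The 10 groupings of 6 libraries, the real one included, are too few for a share under 0.05. They gave 4839 real calls against 0 at most for the wild type response (1 as large), 4756 against 0 in gcn2Δ (1), 4847 against 0 in gcn4Δ (1) and 4823 against 0 in mbf1Δ (1). For the untreated strains they gave 25 against 0 for gcn2Δ (1), 1123 against 1 for gcn4Δ (1) and 9 against 10 for mbf1Δ (2).

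Untreated gcn4Δ differed from wild type in 1123 genes, with a median size of 0.36 on the log2 scale. Against a depth difference as the whole cause, 980 of these calls were kept with the same sign after thinning to equal total counts and 935 after thinning to equal usable depth (total counts times TMM factor), and against GC content 929 were kept after its trend was removed. The share of counts over ribosomal RNA genes cannot be told apart from the deletion: at equal share the median in the called direction was 0.07 and 192 calls were kept, but the groups do not overlap in share (lowest 10.6% in wild type, highest 1.48% in gcn4Δ). A difference in the recovery of poly-A RNA between the groups could therefore account for part of the calls, and an effect of the deletion stays open.

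Hsf1 chaperones responded more than in wild type in gcn2Δ (median 0.76) and mbf1Δ (median 0.89). GC content as the cause is argued against by the larger adjusted p of the 2 interactions with its trend removed, 0.00566 with an estimated correlation. So are the libraries standing apart (0.00705 without them) and a lower untreated level in the mutants (lower of their untreated medians 0.06). In mbf1Δ the share of counts over ribosomal RNA genes is argued against as the whole cause only as far as shares overlap wild type. At equal share the mbf1Δ list level still differed by 0.92 (SE 0.05), and the adjusted p of the list was 0.000479 (camera, estimated correlation). The overlap rests on libraries standing apart, untreated wild type replicate 3 and treated mbf1Δ replicate 1. Without them untreated mbf1Δ had at most 13.5% against at least 15.6% in wild type. Treated mbf1Δ then had at least 17.3% against at most 16.2%, so the share is not fully told apart from this deletion. In gcn2Δ the level differed by 0.69 (SE 0.05), with adjusted p = 0.027 for the list. Untreated gcn2Δ (highest 7.41%) did not overlap untreated wild type (lowest 10.6%), so the share cannot be told apart from that deletion. A stronger chaperone response without GCN2 or MBF1 may be biological, and stays a hypothesis found and tested on the same data.

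Ribosome biogenesis genes fell less than in wild type in gcn2Δ (median 0.90) and gcn4Δ (median 1.17). A response to MMS weakened alike in all groups of genes is argued against by histone genes, which would have fallen less by 0.53 and 0.70 and differed by -0.28 (SE 0.12) and -0.29 (SE 0.1). GC content and the libraries standing apart are argued against by the larger adjusted p with an estimated correlation, 0.0136 with the GC trend removed and 0.0144 without those libraries. At equal share of counts over ribosomal RNA genes the list level still differed by 0.89 (SE 0.08 with log2 share) and 1.17 (SE 0.1), with adjusted p = 0.027 and 0.0104 for the list. Untreated gcn2Δ (highest 7.41%) and gcn4Δ (highest 1.48%) did not overlap untreated wild type (lowest 10.6%) in share. Equal share therefore extends a trend within groups, and the share cannot be told apart from the deletions. A weakening shared by some groups of genes was not tested, so it stays open, as does an effect of the deletions on this group alone. In wild type, gcn2Δ and gcn4Δ the MMS response of the Msn2/Msn4 list had medians of 3.55, 2.47 and 2.52. Ribosomal proteins had -3.15, -2.86 and -2.19, while Hsf1 chaperones had 1.02, 1.77 and 1.15.

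The response of the amino acid list lay below that of wild type, with medians of -1.66 in gcn2Δ, -1.33 in gcn4Δ and -1.38 in mbf1Δ. Its mean level rose by 0.80 in wild type and fell by 1.04, 0.59 and 0.66 in those mutants. It fell less in mbf1Δ than in gcn2Δ (median difference 0.33), while the difference in mean level had exact permutation p = 0.14 (adjusted p = 0.168). Ribosomal proteins had 1.00 in gcn4Δ against wild type, -0.35 in mbf1Δ against gcn2Δ, and -1.0 and -0.66 in mbf1Δ and gcn2Δ against gcn4Δ. Ribosome biogenesis had -0.45 in mbf1Δ against gcn2Δ and -0.75 in mbf1Δ against gcn4Δ. Against gcn4Δ, Hsf1 chaperones had 0.83 in mbf1Δ and 0.68 in gcn2Δ, and synthetases -0.47 and -0.36. Of these, ribosomal proteins in mbf1Δ against gcn2Δ had adjusted p = 0.0492 with an estimated correlation, under 0.05 in 4 of 12 omissions of a single library. Ribosomal proteins and synthetases in gcn2Δ against gcn4Δ had 0.0574 each without treated gcn2Δ replicate 3. The gcn4Δ libraries did not overlap those of any other strain in rRNA-locus share. In contrasts with gcn4Δ the share therefore cannot be told apart from the strain.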

How the results depend on the processing

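GC-trend removal, the rRNA-locus share as a covariate, leaving out genes over rRNA genes or the 3 libraries standing apart, thinning to equal depth and single-library omissions in the list tests were added after the data were seen; the other settings were planned. Where a setting changed a value below, the cause was not tested. The level and list tests were not run under every setting: DESeq2, limma on TPM, upper quartile, effective length and thinning were not run for list tests.

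Of 314 called gene values, direction and call held in 312 with DESeq2's size factors, 309 with upper quartile, 314 with no filter, 313 with effective length offsets, 307 with a replicate block (replicate numbers do not pair the libraries), 307 with a GC trend removed, 300 with the rRNA-locus share, 306 after thinning, 299 of 304 by DESeq2, 276 by limma on TPM, 300 in fits to the compared groups alone, and 278 at an adjusted p under 0.01. With single libraries left out 2952 of 3102 held and 37 genes had a call that weakened. Of 182 list tests 178 held with DESeq2's size factors, 182 with the block, 172 with the GC trend removed, 159 with the rRNA-locus share and 126 with an estimated correlation.

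By limma on TPM, the calls were 1295, 1315 and 794 for the gcn2Δ, gcn4Δ and mbf1Δ interactions, 2860, 4288 and 14 for the untreated strains in that order, and 129, 1312 and 954 for mbf1Δ against gcn2Δ, mbf1Δ against gcn4Δ and gcn2Δ against gcn4Δ. At an adjusted p under 0.01 they were 1344 and 782 for the gcn4Δ and mbf1Δ interactions, 9, 465 and 5 untreated, and 158, 1598 and 1034 between mutants. With the rRNA-locus share they were 3086 and 2289 for the gcn4Δ and mbf1Δ interactions, 18 for untreated mbf1Δ, 684 for mbf1Δ against gcn2Δ and 3414 for gcn2Δ against gcn4Δ, and the gcn2Δ and mbf1Δ interactions shared 1898. Without the libraries standing apart they were 2031 and 2502 for untreated gcn2Δ and gcn4Δ and 597 for mbf1Δ against gcn2Δ. Untreated gcn2Δ had 94 with upper quartile, 76 with effective length offsets, 93 with the GC trend removed and 395 by DESeq2, and untreated mbf1Δ 17 by DESeq2. With the GC trend removed mbf1Δ against gcn2Δ had 602, and in fits to the compared groups alone it had 103 and untreated mbf1Δ 5.

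Single-library omissions gave 7 to 1156 for untreated gcn2Δ, 517 to 1916 for untreated gcn4Δ, 5 to 12 for untreated mbf1Δ and 221 to 479 for mbf1Δ against gcn2Δ. They gave 3 to 7 lists called in untreated mbf1Δ, with 3 without untreated wild type replicate 1, and -1.49 to -1.39 for the amino acid level of mbf1Δ against wild type. GCN2 in the mbf1Δ response was -0.19 without treated mbf1Δ replicate 1.

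With an estimated correlation the lists called were 7 in wild type, 3, 3 and 2 in the gcn2Δ, gcn4Δ and mbf1Δ interactions, 0, 1 and 0 in the untreated strains, and 3 each for mbf1Δ against gcn2Δ and for gcn2Δ against gcn4Δ. With the rRNA-locus share the direction reversed in untreated gcn2Δ for sulfur (adjusted p = 0.129, 0.576 with an estimated correlation) and nitrogen genes (0.0107), and in untreated gcn4Δ for ribosomal proteins (0.42 and 0.984), sulfur (0.0211) and histones (0.419 and 0.863). Without the libraries standing apart it reversed for Msn2/Msn4 in untreated mbf1Δ (0.000645), all by camera in limma.

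As mean log2(TPM + 1) the amino acid level responses were 1.42, -0.40, 0.02 and 0.06 in wild type, gcn2Δ, gcn4Δ and mbf1Δ, and the differences -1.82, -1.40 and -1.36 from wild type and 0.46 for mbf1Δ against gcn2Δ. With the GC trend removed the gcn4Δ response was -0.66. By limma on TPM, where all genes shifted by 0.554 in wild type, 0.546 in gcn2Δ and 0.576 in gcn4Δ, so that a sign says nothing relative to the bulk, the wild type response reversed for GCN2 (0.45), SEM1 (0.11), SEC61 (0.08) and TRX1 (0.23), and that of SNZ1 in gcn2Δ (0.55) and gcn4Δ (0.40). With the rRNA-locus share APQ13 in untreated gcn4Δ reversed to -0.19. At the depth here, 61.6% to 93% of 1.5-fold changes were recovered in simulated data. The simulated libraries varied independently and none stood apart, so recovery in the real libraries may be lower.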

Other observations

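The neighbours of the deleted genes were looked up after the values of MRX10 and MUM3 were seen. In untreated gcn2Δ cells MRX10 lay lower (-1.14, SE 0.11, adjusted p = 1.32e-06) and DPP1 had 0.02 (adjusted p = 0.933). In untreated gcn4Δ cells YEL009C-A had 0.63 (adjusted p = 0.17) and YEL008W -0.26 (adjusted p = 0.374). In untreated mbf1Δ cells MUM3 lay higher (1.58, SE 0.13, adjusted p = 1.26e-07) and BUD7 had 0.26 (adjusted p = 0.0795, edgeR's quasi-likelihood test). MRX10 lies 314 bases from GCN2 and MUM3 191 bases from MBF1. With 200 bases added on each side, their gene models would meet that of the deleted gene. Their values may therefore hold reads from the deleted locus.

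SAG1, the alpha-agglutinin gene, had 45.6 ± 4.48 CPM (SD, n = 3) in untreated and 102 ± 4.56 in treated wild type cells, 39.6 and 84.8 in gcn2Δ, 40 and 109 in gcn4Δ, and 45 and 95.2 in mbf1Δ. The share of counts over ribosomal RNA genes after MMS was 15.4% in wild type, 12.9% in gcn2Δ, 0.489% in gcn4Δ and 14.6% in mbf1Δ.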
